A study of Mus musculus with 10 samples.

How the data were processed

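The series holds 10 single-colour microarrays of RNA from extracellular vesicles of mouse brain. Per the labels' protocols, vesicles were separated from whole brain by differential ultracentrifugation and their total RNA was purified with a kit. About 3 µg of RNA was submitted for the arrays, where it was amplified and copied into Cy3-labelled cRNA. The 10 samples were grouped by the treatment named in their labels, with 5 Control and 5 CIE samples. Each sample is called by its group and by the number in its title, which runs from 1 to 10 over both groups. The labels do not say whether each sample came from 1 animal or from several, so the p-values measure only the spread between these samples, which may be technical.

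The scanner files give a spot's brightness as a linear intensity, which the authors obtained with Agilent Feature Extraction 11.0.1.1, per the file headers. The processed intensity used here is background-subtracted by that program, per the file headers. The authors also deposited a table for the same arrays whose scale is not stated, and which was taken as log2 because its columns correlated with quantile-normalised log2 scanner values at r between 0.988 and 0.991. Each of its 10 columns had a median of 4.60 and the same 75th percentile of 6.66, and its ranks followed those of the matching scanner file with a rank correlation between 0.990 and 0.999, above the best correlation with any other array. How that table was normalised is not given in the sources used here. Equal medians and 75th percentiles in all columns are what quantile normalization leaves. The table may therefore not be a scaling separate from the quantile normalization tried below, and it served as an alternative only.

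Each array carried 62976 spots, of which 61537 belonged to 60823 non-control probes. Spots with an outlier flag (between 27 and 150 per array) were left out, and the remaining spots of a probe were averaged on the log2 scale. No spot was saturated. Log2 intensities were centred on the 75th percentile of all non-control probes of the array, since over 50% of the probes were well above background on every array. Values given below are therefore log2 units relative to that percentile, and values of different probes are not comparable with each other. The number of arrays limits the precision: the median standard error of a group difference was 0.302 log2 units, and the median half-width of its 95% interval was 0.663, a factor of 1.58.

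Probes well above background on at least 5 of the 10 arrays, whatever their group, were tested. This left 43084 probes, 70.8% of those on the array. CIE was compared with Control by limma 3.58.1 (lmFit and eBayes, R 4.3.3), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Where a measure had 1 value per array, an exact two-sided permutation test over all 252 relabelings of the 10 arrays was used, and 9 such measures were adjusted together. The same measures were also compared inside pairs of consecutive sample numbers over all 32 sign flips, and the correlation between arrays over the 16 distinct label swaps inside those pairs, both chosen after seeing the data. So were the comparisons of the lincRNA, P and UP series with the AP series, and the block fits under all 24 pairings of a Control with a CIE array without Control 7 and CIE 8. The permutation test of array order drew 100000 reorderings.

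The files used here name probes by the vendor's own identifiers and do not pair most of them with genes. Only 50 probes carry a public transcript identifier, and 46 of these matched a gene symbol in a RefSeq table of assembly GRCm38.p6, used for names only. Of these genes, 45 are protein-coding and 1 is a transcribed pseudogene, and 43 passed the filter. Probes whose identifier contains LNC or lincRNA were taken as long non-coding RNA (lncRNA), 29618 in number, while the series marked AP (22359 probes), P (7912) and UP (752) have no class stated in the files. Counts of mRNA below cover the named protein-coding genes alone. For the comparison of classes, the AP series was set against the LNC series, with its class left open. No coordinates are given, because the array files and the reference table use different builds.

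Genes were named by a rule fixed before the data were examined. The rule takes mRNAs past the threshold with a change of at least 1.5-fold, up to 12 in each direction, and lncRNAs likewise, up to 5 in each direction. Where too few pass, places are filled by the smallest unadjusted p with the same minimum fold, in equal numbers per direction, and such genes are said not to have passed. It adds up to 4 members of each gene list described, and names no gene whose probes differ in sign past the threshold without saying so. Since few genes can be named at all, others of the 43 were described after their values were seen, and are marked so. The values of 1 named gene are not reported here, although counts over the 43 include it. Of lncRNA probes, which have no gene name here, only 2 per direction are given, by identifier. The 38 gene lists fixed with it needed 5 tested members for a test (camera). No list had more than 2, so none was tested, and only the 5 lists with a tested member are described.

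The fit was tested on simulated data. Arrays were drawn for 42857 probes from the real means and spreads of the comparison of CIE with Control, with 100 probes changed 2-fold and 100 changed 4-fold. The fit recovered 8 of the 2-fold and 62 of the 4-fold changes and called 3 unchanged probes. With the same changes added to the real arrays, it recovered 2 and 53, and called 0 others.

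Alternatives fixed before the data were examined were quantile normalization, median centring, the percentile over probes well above background on all 10 arrays, normexp background correction with an offset of 50 followed by quantile normalization, the authors' table, no filter and a stricter filter on dim probes, an intensity trend with robust eBayes, array weights, an unmoderated equal-variance test, slide as a block, each array left out, and an unadjusted threshold with a minimum fold. Normexp used the median spot signal, because the files used here give no mean spot signal. Each named gene had 1 probe, so that another choice of probe per gene could not be tried. The arrays lay on 2 slides, which the file headers distinguish. Slide 1 held 5 Control and 3 CIE arrays, and slide 2 held CIE 8 and CIE 10. On slide 1, Control 1, 4, 6 and 7 filled row 1, and Control 9, CIE 2, CIE 3 and CIE 5 filled row 2. Place therefore moved with exposure there as well, so that comparisons within slide 1 do not separate them. The share of probes higher in CIE with array weights or with slide as a block, the class comparison with slide as a block, blocks of consecutive sample numbers, slide 1 alone, and the comparison without Control 7 and CIE 8 were added after seeing the data.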

Results

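RNA carried by extracellular vesicles of the brain was measured in male C57BL/6J mice after chronic intermittent ethanol (CIE) vapor, an inhalation model of alcohol dependence, or after room air (Control). Exposure lasted 8 h per day on 5 days per week for 4 weeks, and whole brains were taken right after the last exposure. The question posed by the design is whether the mRNA and lncRNA content of these vesicles differs after ethanol. Each group had 5 arrays. Between 61.7% and 77.3% of the 60823 probes were well above background on an array. The 75th percentile of the signal ranged from 69.7 to 192 intensity units, a 2.76-fold span.

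No named gene and no lncRNA probe passed the test of CIE against Control. Of the 43 genes with a named and tested probe, the one with the largest difference was Gabrg1, which encodes the gamma-1 subunit of the GABA-A receptor. Its level was 1.41 ± 0.99 (SD, n = 5) log2 units in CIE against 2.28 ± 0.99 in Control, a log2 difference of -0.87 with a standard error of 0.55 and a 95% interval from -2.07 to 0.34 (limma adjusted p = 0.989). Chgb, the dense-core granule protein chromogranin B, was at 4.44 ± 0.74 in CIE against 5.04 ± 0.44 in Control, a log2 difference of -0.60 with a standard error of 0.36. On the other side, Cpt1a, which brings fatty acids into mitochondria, had a log2 difference of 0.67 with a standard error of 0.52, and Nup50, a protein of the nuclear pore, one of 0.61 with a standard error of 0.73. None of these 4 genes passed the threshold, each with a limma adjusted p of 0.989, and the adjusted p was 0.971 for each when adjusted over the 43 named genes alone.

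Across the whole array, limma called 0 of 43084 probes, while 921 lay at an unadjusted p under 0.05, where 5% of the probes is 2154. Other splits of the 10 arrays gave a median of 1244 and up to 12220, so that 2154 is no benchmark for these arrays. The unmoderated test also called 0, with 1082 at the unadjusted level. That count of 921 was 402 without Control 9, 412 without Control 4, 2345 without CIE 10 and 2347 without CIE 5. The 42 tested protein-coding genes held 0 probes under the unadjusted level, and the 20502 lncRNA probes held 455. With slide as a block the call of 0 probes was the same, with 2172 under the unadjusted level, and within slide 1 alone, with 5 Control and 3 CIE arrays, it was 0 with 2474. Slide 2 held CIE arrays only, so that any difference with slide as a block rests on slide 1 alone, without CIE 8 and CIE 10. With consecutive sample numbers as a block, limma also called 0, but 6389 probes lay under the unadjusted level, where other label swaps inside the pairs gave up to 5067.

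**Figure D1:**
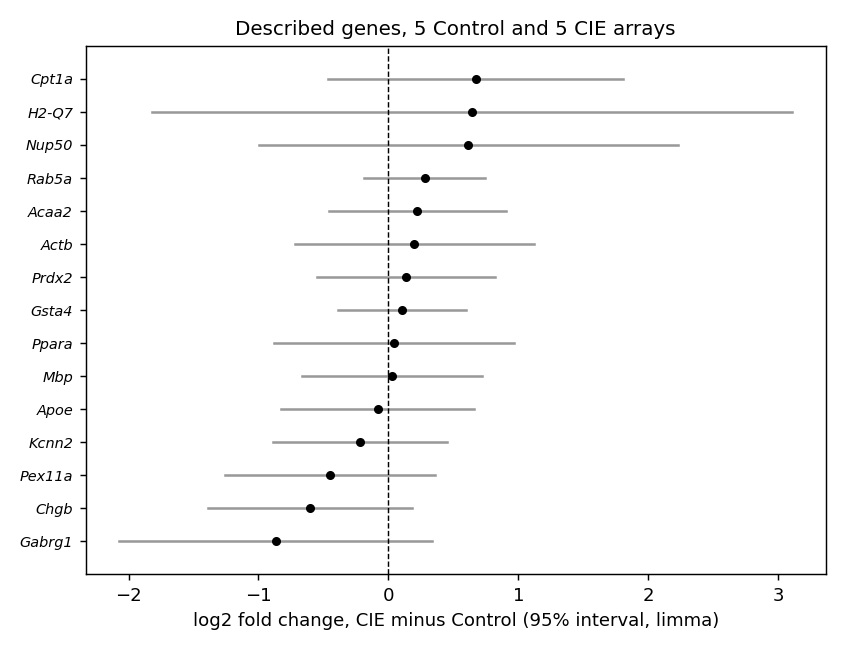
Log2 fold change of CIE over Control for 15 of the tested genes, 1 line per gene, with points for the limma estimate and lines for its 95% interval (5 arrays per group). All 15 intervals include 0, from Gabrg1 at -0.87 to Cpt1a at 0.67.

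Genes of neuronal signalling were represented by few probes. Gabrg1 was the only tested member of the 15 GABA-A receptor subunit genes listed, and its difference was -1.33 with slide as a block and -0.52 without Control 9. It lay below 0 under each of the 26 settings run for it. Kcnn2, a small-conductance calcium-activated potassium channel and the only tested member of the list of ion channels, was at -1.14 ± 0.51 (SD, n = 5) in CIE against -0.92 ± 0.47 in Control, and did not pass. Its difference of -0.22 was -0.07 without CIE 2, -0.40 without CIE 10 and -0.39 with slide as a block. Adjusted over the list alone, 0 members of these lists passed in the comparison of all 10 arrays without a block, where Gabrg1, alone in its list, had a limma p of 0.142. That p lay under 0.05 in 6 of the 26 settings, among them 0.04996 with slide as a block, 0.0475 within slide 1 and 0.0385 without CIE 10. It ranged from 0.00738 with consecutive sample numbers as a block to 0.339. The values with slide as a block and within slide 1 rest on the same difference of -1.33, since slide 2 held no Control array.

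Of the 16 myelin and 15 reference genes listed, 1 each was tested, Mbp and Actb. Both were well above background on all 10 arrays, and their group differences lay within the spread between samples. Mbp, myelin basic protein, was at 7.55 ± 0.52 (SD, n = 5) in CIE and 7.52 ± 0.51 in Control, a log2 difference of 0.03 with a 95% interval from -0.66 to 0.72. Its sign turned to -0.02 with slide as a block. Actb, the cytoskeletal beta-actin and the only tested reference gene, was at 5.62 ± 0.87 in CIE and 5.42 ± 0.55 in Control. Its difference of 0.20 turned to -0.19 with slide as a block and to -0.17 without CIE 8. Actb was highest on Control 7 (6.39) and CIE 8 (7.10), where control probes for human transcripts were also brightest. Without both arrays its difference was 0.07. Apoe, an apolipoprotein of lipid transport in brain, chosen after its values were seen, was at 6.23 ± 0.65 in CIE and 6.31 ± 0.46 in Control. Its difference of -0.08 turned to 0.08 under quantile normalization. Adjusted over the list alone, 0 members of the myelin and reference lists passed.

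Of the antioxidant genes, 2 of 24 were tested and neither passed. Prdx2, a peroxiredoxin, was at 3.48 ± 0.64 (SD, n = 5) in CIE and 3.35 ± 0.34 in Control, and Gsta4, a glutathione transferase acting on lipid peroxidation products, at -0.26 ± 0.40 and -0.36 ± 0.16. The Prdx2 difference of 0.14 turned to -0.08 without CIE 2, and the Gsta4 difference of 0.10 turned to -0.05 with slide as a block. Adjusted over the list alone, 0 passed.

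Other genes were chosen after their values were seen, and none passed. Among genes of fatty acid handling, Ppara, a lipid-sensing nuclear receptor, had a log2 difference of 0.04 with a standard error of 0.42, which turned to -0.27 with slide as a block. Acaa2, a thiolase of mitochondrial beta-oxidation, had one of 0.22 with a standard error of 0.31, and Pex11a, which acts in peroxisome division, one of -0.45 with a standard error of 0.37. Without CIE 2 the Acaa2 difference was 0.03 and that of Pex11a -0.74, and with slide as a block they were 0.38 and -0.16. The Cpt1a difference of 0.67 shrank to 0.15 without CIE 2, and that of Nup50 from 0.61 to -0.02. With slide as a block these 2 differences grew to 1.13 and 1.33. Rab5a, a small GTPase of early endosomes, had a difference of 0.28 with a standard error of 0.21, and of 0.17 without Control 4. H2-Q7, a major histocompatibility gene with closely similar copies that the probe may share, was at 2.83 ± 2.26 (SD, n = 5) in CIE and 2.18 ± 1.90 in Control. Its difference of 0.65 became 1.75 with slide as a block and -0.15 without CIE 2. Il2, Tyr and Atg3 were well above background on too few arrays to be tested.

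The lncRNA probes with the smallest p in each direction are given by identifier. ASMM10LNC1A100177954V4 had a log2 difference of 1.03 with a standard error of 0.27, and ASMM10LNC1A100084059V4 one of 1.08 with a standard error of 0.28. Both were dim in Control, well above background on 2 and 1 of its 5 arrays against 5 of 5 in CIE, so that these differences rest in part on signal near background. In the other direction, ASMM10LNC1A100104559V4 was bright in both groups, at 7.85 ± 0.03 (SD, n = 4) in Control and 6.78 ± 0.51 (SD, n = 5) in CIE, and mouselincRNA0561+_P1V4 had a log2 difference of -0.72 with a standard error of 0.20, which rests in part on signal near background, since it was well above background on 2 of the 5 CIE arrays against 5 of 5 in Control. None of the 4 passed, each with a limma adjusted p of 0.989. Of the 20502 lncRNA probes, 41.1% lay higher in CIE, against 42.9% of all tested probes. That share depends on the scaling, and for all tested probes it was 45.9% under quantile normalization, 46.6% in the authors' deposited table and 48.4% under normexp followed by quantile normalization. Of the 921 probes under the unadjusted level, 201 lay higher in CIE, a share of 21.8%, which was 32.6% under quantile normalization and 35.6% in the authors' deposited table. Without CIE 2 it was 50.6% (393 of 776), without CIE 8 39.0% (277 of 710) and without CIE 5 13.7% (321 of 2347).

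LNC probes were set against probes of the AP series to ask whether classes of RNA moved apart. The median log2 difference was -0.06 over 19731 LNC probes and -0.01 over 17219 AP probes. The gap of 0.05 between the medians did not exceed that of other labelings of the arrays (exact permutation p = 0.222, two-sided, n = 5 per group). Such relabelings ignore the pairs of consecutive sample numbers, inside which no gap between series was tested. Without CIE 2 the gap was 0.01, and under normexp followed by quantile normalization 0.02. Within slide 1 it was 0.06 (exact permutation p = 0.304). The lincRNA series had a median of -0.16, with 29.6% of its 771 probes higher in CIE, and the P series one of -0.16, with 30.1% of 4949, against 48.8% in the AP series. Their medians lay -0.15 from that of the AP series, for lincRNA with an exact permutation p of 0.159 and for P of 0.167 (both 0.296 after adjustment over 4 series). Under normexp followed by quantile normalization both gaps were -0.05, without CIE 2 they were -0.05 and -0.08, and without Control 1 -0.21 and -0.22. The gap of the UP series was -0.09 (exact permutation p = 0.413), -0.02 without Control 7 and -0.19 without CIE 8. The AP series was also brighter, with a median level of -0.83 against -1.11 for LNC, -1.21 for P, -1.64 for lincRNA and -1.74 for UP. Whether brightness underlies the gaps was not tested.

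The share of probes well above background was 67.4% ± 5.0 (SD, n = 5) in CIE and 71.6% ± 4.0 in Control, a difference of -4.16 percentage points (exact permutation p = 0.190, two-sided, 0.414 after adjustment over 9 measures). Within slide 1 the difference was -4.86 points (exact permutation p = 0.0893). The share was lower in the CIE array in 5 of the 5 pairs of consecutive sample numbers, as was the 75th percentile of the signal (for both, exact p = 0.0625 over 32 sign flips, the smallest they can give, 0.1125 after adjustment over 9 measures). The difference in the share was -6.12 points without CIE 10 (exact permutation p = 0.0397), the only single array whose removal took this value past 0.05.

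The mean Pearson correlation across probes was 0.944 within groups and 0.948 between groups (difference -0.00407, exact permutation p = 0.468, two-sided, n = 5 per group). Within slide 1 that difference was 0.00691 (exact permutation p = 0.464), and its sign also turned without CIE 5 (0.00187) and without CIE 10 (0.00218). The 5 pairs of consecutive sample numbers, with a mean r of 0.978, each join a Control with a CIE array and so enter the mean between groups. Without them that mean was 0.941 over 20 pairs of arrays, and the difference turned to 0.00336 (exact p = 0.0625 over 16 label swaps inside the pairs, the smallest they can give). The highest correlation, 0.985, joined CIE 5 with Control 6, and the lowest was 0.897. The mouse GAPDH 3' control probe, for a glycolytic enzyme, was at 4.93 ± 0.64 (SD, n = 5) in CIE and 4.61 ± 0.41 in Control (exact permutation p = 0.397). Its 3' minus 5' signal, a sign of RNA integrity, was 0.90 ± 0.29 in CIE and 0.58 ± 0.32 in Control, a difference of 0.32 (exact permutation p = 0.143, 0.414 after adjustment over 9 measures). It was higher in the CIE array in 5 of the 5 pairs (exact p = 0.0625), and within slide 1 the difference was 0.45 (exact permutation p = 0.0714). Mouse PGK1 3' minus 5' was not tested. Its 5' probe was dim, between -4.43 and -3.18, where Il2, at -4.00 in Control, was too dim to test. The PGK1 difference may therefore rest in part on signal near background, and it did not go one way in the pairs. It was lower on CIE 5 than on Control 6 (6.98 against 7.30) and on CIE 8 than on Control 7 (5.58 against 6.35), and higher in the CIE array of the other pairs. Control probes for human GAPDH and PGK1 were brightest on Control 7 and CIE 8, where Human-GAPDH_5 stood at 2.80 and 3.49 against at most 0.47 elsewhere. Without both arrays, limma again called 0 probes, with 601 under the unadjusted level.

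**Figure D2:**
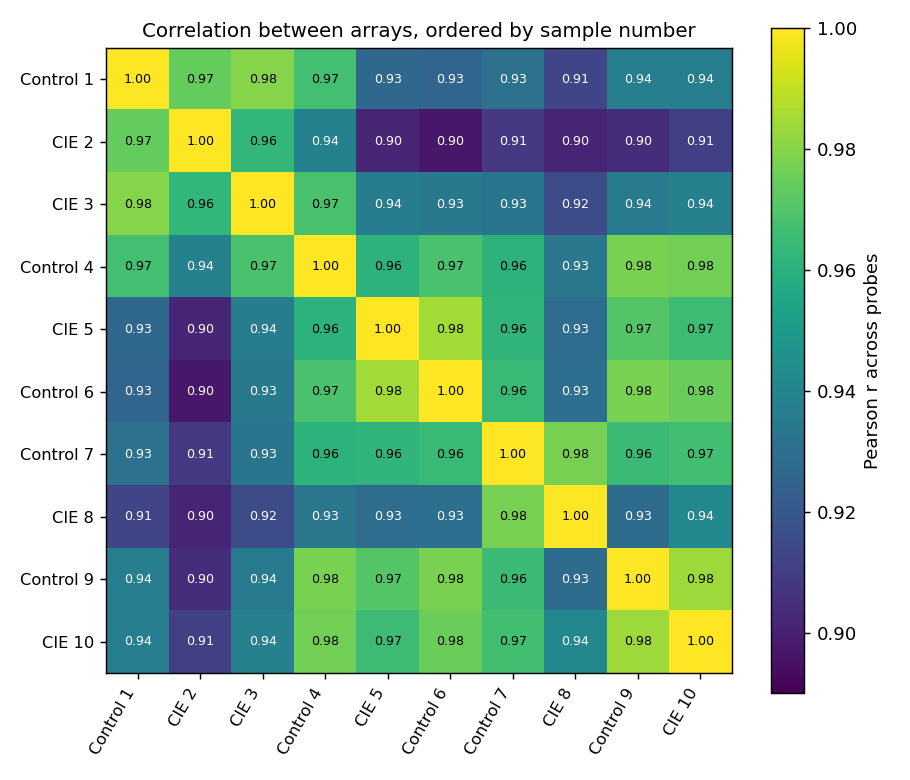
Pearson correlation across the 42857 probes with a value on all arrays, for each pair of the 10 arrays, ordered by sample number on both axes; colour and printed number give r. The value between CIE 5 and Control 6, 0.985, is the highest, and that between the neighbouring CIE 8 and Control 9 is 0.929. This order interleaves the groups, so that a block of Control or CIE arrays could not show.

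**Figure D3:**
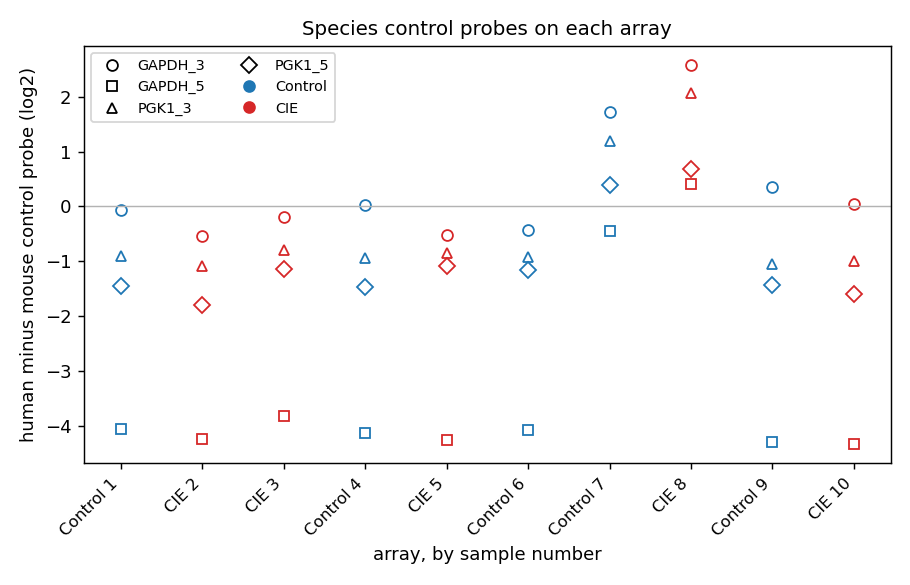
Human minus mouse control probe signal (log2, vertical axis) on each of the 10 arrays, with marker shape for the GAPDH and PGK1 probe pairs and colour for the group; only differences between arrays can be compared, not the level of a pair. All 4 pairs lie highest on Control 7 and CIE 8, where GAPDH_5 reached -0.44 and 0.40.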

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

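All tests of this part except the counts over other splits of the 10 arrays were chosen after the result was seen. Over 114 groups of 5 values (array measures, species control probes and named genes, each in each exposure group), 6 had 1 array far from the other 4, where chance alone gives about 1 in 20 groups, or 5.7. Human-GAPDH_5 stood at 2.80 on Control 7 against at most 0.47 on the other Control arrays, and at 3.49 on CIE 8 against at most 0.36 on the other CIE arrays. Human-PGK1_5 stood at -2.54 on CIE 8 against at most -4.98. Actb stood at 6.39 on Control 7 against at most 5.34 on the other Control arrays. On CIE 8 Actb was also high, at 7.10 against at most 5.55 on the other CIE arrays, which the same test did not flag. Gm9789 stood at -2.38 on Control 1 against at least -1.82, and Nup50 at 1.1 on Control 1 against at most -0.78 on the other Control arrays.

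Control probes for human GAPDH and PGK1 were brighter on Control 7 and CIE 8, and 4 of the 4 differences between the human and the mouse probe of a transcript end were higher on both arrays than on each of the other 8. More transcript of the mouse genes is argued against, since 0 of the 4 mouse probes were higher on both arrays. Mouse-GAPDH_3 was lowest on these arrays (4.15 and 4.06 against at least 4.31). So were Mouse-GAPDH_5 (3.25 and 3.09 against at least 3.87) and Mouse-PGK1_3 (2.61 and 2.35 against at least 2.85). Lower mouse signal is therefore part of those human minus mouse differences. The 2 arrays lay on different slides. Less specific hybridisation stays open: 1 of the 4 differences between the rat and the mouse probe, that of GAPDH_5, was higher on both, and so was the mean of the 4 (-2.81 and -2.53 against at most -3.11), while the other 3 were not. Human RNA in those 2 preparations is a candidate explanation too, and 381 of 42857 probes exceeded all other arrays by at least 1.5 log2 units on both, against at most 143 for any other pair of arrays. No biological explanation was tested, since 1 array of each exposure group is involved.

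Arrays resembled each other by the sample number in their titles, with a correlation of -0.500 between the number gap of 2 arrays and their r (permutation p = 0.0062, two-sided), which argues against a chance order. Control 7 and CIE 8 lay on different slides, as did Control 9 and CIE 10. Yet the arrays of each pair were each other's closest (r = 0.978 and 0.984), which argues against place on the slide for these pairs. For the pairs on slide 1, place stays open. On slide 1, the gap in reading order showed no clear relation to r (correlation 0.171, permutation p = 0.349), while the number gap did (-0.558, permutation p = 0.0138). Reading order does not measure distance across rows. Arrays 1 and 2, 3 and 4, and 5 and 6 were diagonal neighbours there. Exposure is argued against as the source, since each of the 5 pairs of consecutive numbers joins a Control with a CIE array, and their mean r exceeded that within groups by 0.0337. For 7 of the 10 arrays the closest array had a neighbouring number. Control 1 and CIE 3 were instead closest to each other (r = 0.980), and Control 4 was closest to Control 9 (0.978). The 5 pairs of consecutive numbers had a mean r of 0.978, the highest among all 945 ways to pair the 10 arrays (exact p = 0.00106, the smallest that pairing can give). A shared step of dissection, vesicle isolation or RNA handling may underlie this, which the labels do not record and no test here addressed.

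With consecutive numbers as a block, limma called 0 probes, but 6389 lay at an unadjusted p under 0.05 against 921 without the block, and 12.7% of the possible orders of the labels would put 1 array of each group in all 5 pairs. Human-probe signal of Control 7 and CIE 8 is argued against as the whole source of the rise, since without both arrays the count went from 601 to 4285 with the block. Of the 24 ways to pair each Control with a CIE array, only 1, that by consecutive numbers, gave as many, with 2048 as the highest other. That comparison of pairings is not separate from the high r of the consecutive pairs, since a block of similar arrays leaves less spread. Among the 16 ways of swapping labels inside the pairs, 1, the real one, gave as many as the real 6389, the highest other gave 5067, and with 16 ways, or the 8 without both arrays (4285 against at most 2859), no share under 0.05 can be reached. Array signal and GAPDH 3' minus 5' within the pairs went one way in 5 of 5, with a lower 75th percentile of the signal and a higher GAPDH 3' minus 5' in the CIE array. Mouse PGK1 3' minus 5', which may rest in part on signal near background because its 5' probe was dim (-4.43 to -3.18), did not go one way. It was lower on CIE 5 than on Control 6 (6.98 against 7.30) and on CIE 8 than on Control 7 (5.58 against 6.35), and higher in the CIE array of the other pairs. The signal and the GAPDH difference cannot be told apart from an effect of ethanol, since they move with exposure in every pair.

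Without a block, 59 of 100 splits of the arrays, the real one included and the others drawn, gave at least its 921 probes at an unadjusted p under 0.05, and the highest other gave 12220, so chance cannot be excluded. For probes past the adjusted threshold, 100 of 100, again with the real one, gave at least its 0, which any split must, so that this count decides nothing, and the highest other was 1253. Both highest values came from the split that set arrays 1, 2, 3, 7 and 8 apart, which points to a structure of the samples. It follows neither slide nor exposure.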

How the results depend on the processing

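Blocks of consecutive numbers, array weights and slide blocks for shares and classes, slide 1 alone and the comparison without Control 7 and CIE 8 were chosen after seeing the data. By limma, and by the unmoderated test (1082 at an unadjusted p under 0.05), 0 probes passed the adjusted threshold under each of the 21 alternatives fixed before and the 5 added ones that kept it, for all probes, lncRNA probes, protein-coding genes and named genes alike. With an unadjusted p under 0.05 in its place, 153 probes (lncRNA 65) had a fold of at least 2 and 707 (lncRNA 346) of at least 1.5, the threshold itself being looser. The count at an unadjusted p under 0.05, 921, was 1599 with no filter on dim probes, 2172 with slide as a block, 2474 within slide 1, 601 without Control 7 and CIE 8, 6389 with consecutive numbers as a block, 6055 with that block under quantile normalization and 4285 with it without Control 7 and CIE 8. Leaving out 1 array gave from 402 (without Control 9) to 2347 (without CIE 5), with 412 without Control 4 and 2345 without CIE 10. The share of probes higher in CIE, 42.9%, was 48.7% with no filter. The correlation within minus between groups, -0.00407, was 0.00691 within slide 1, 0.00187 without CIE 5 and 0.00218 without CIE 10, and with 1 array left out ran from -0.0100 to 0.00218. The difference in probes well above background ran from -6.12 (without CIE 10, exact permutation p = 0.0397) to -2.73 points with 1 array left out. Where no cause is named, the cause was not tested. No named gene passed over all tested probes. None moved by 1 SD over the 10 arrays, which leaving out 1 array cannot reach, so that this says little of stability. The largest move was 1.11 log2 units, with slide as a block, and at most 14 of 43 signs turned, without CIE 2. List tests had too few members under any setting. Signal over background limits the test to 70.8% of probes.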

Other observations

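All values and tests of this part were chosen after the data were seen. Several named genes varied more between arrays than between exposure groups. H2-Q7 stood at 4.96 on Control 1, 6.02 on CIE 2, 4.36 on CIE 3 and 3.38 on Control 4, and between 0.68 and 1.65 on the other 6 arrays. Gsdmd, the pore-forming protein of pyroptosis, stood at -0.88 on Control 1 and -0.21 on CIE 2, and at -3.51 on CIE 8. Gabrg1 stood at 1.09, 0.34 and 0.66 on Control 1, CIE 2 and CIE 3, and at 3.66 on Control 9.

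Taking consecutive sample numbers as pairs, 4 of the 43 named genes had the same sign in all 5 pairs, where independent chance signs would give 2.69. Gabrg1 and Chgb were lower in the CIE array in 5 of 5 pairs, as was Kcnn2. With the pairs as a block, 4 named genes lay at an unadjusted p under 0.05, Gabrg1 and Chgb lower in CIE and H2-Q7 and Nup50 higher, the latter 2 in 4 of 5 pairs each. The standard error of the difference was 0.26 in place of 0.55 for Gabrg1, 0.19 in place of 0.36 for Chgb, 0.20 in place of 1.12 for H2-Q7 and 0.25 in place of 0.73 for Nup50. The limma adjusted p was then 0.265 for Gabrg1, 0.272 for H2-Q7, 0.273 for Chgb and 0.309 for Nup50, for each the lowest of a range up to 1.00 over its settings. None of the 4 passed over all tested probes.

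Cep41, a protein of cilia, stood at 0.44 on Control 7 and 1.14 on CIE 8 and at most at -1.46 on the other 8 arrays, and Lhx1, a transcription factor, at 0.61 and 1.36 against at most -0.45. In all, 4 named genes, Actb among them, were highest on those 2 arrays. The other pairs of arrays had 0.886 such genes on average and at most 6. Among the probes that exceeded all other arrays by at least 1.5 log2 units on Control 7 and CIE 8, the UP series had 18 of its 286 probes (6.29%) and the AP series 185 of 17133 (1.08%).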
